A study of Mus musculus with 6 samples.

How the data were processed

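Gene expression was measured in total RNA from the epithelium of the common bile duct of C57BL/6 mice that carry an inducible Fgf10 construct, named iFGF10 in the labels. Per the labels' protocols, 3 samples came from mice that drank 0.02% doxycycline in water for 5 days (DOX+) and 3 from mice that drank water alone for 5 days (DOX-). Doxycycline is an antibiotic used to switch on genes placed under a tetracycline-controlled promoter. The series design states n = 3 mice in each condition. The descriptions of the DOX- samples also carry names that start with WT followed by 2 numbers, while their source names call them untreated iFGF10 mice, so whether the controls carried the construct, and whether each is 1 mouse or a pool, stays open. No group of mice without the construct that drank doxycycline was analysed here, so a difference between the groups can come from the drug as well as from the induced gene. Each RNA was labelled with Cy3 and hybridised to 1 Agilent 1-colour array of 60-base probes.

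The scanner files hold spot intensity, made by the authors with Agilent Feature Extraction, version 10.7.1.1 per the file headers and version 9.5.1.1 per the submitters' processing notes. Per the file headers, the processed intensity was background-subtracted and detrended within each array, and nothing was adjusted between arrays. The deposited files also hold raw mean spot intensity, local background intensity and 0 or 1 flags for spots well above background, saturated or non-uniform. All 6 arrays were on 1 slide and came from 1 scan, so no slide or scan batch could be tested. The 3 DOX+ arrays and DOX- replicate 1 shared the first row of the slide, and DOX- replicates 2 and 3 lay in the second row. A further table holds the authors' processed intensity values for the same 56605 probes. These were on a linear scale, and their sorted columns agreed within a relative difference of 0.00034, as quantile normalisation gives; the software that did this is not given in the sources used here. The correlation of each column with its own array's log2 intensity lay between 0.998 and 0.99999 across probes, and each column's median was 57.79. No scale, centring or direction of that table remained unknown.

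Each array held 59305 non-control spots. The share of them well above background was 59.93%, 61.9% and 60.37% on the DOX+ arrays and 60.61%, 59.39% and 55.93% on the DOX- arrays, no spot was saturated, and 50 to 64 spots per array were left out as outliers. The 75th percentile of the processed intensity was between 666.16 and 910.07. The number of arrays, 3 per group, limits the precision: the median standard error of a log2 difference was 0.185. Because the labels do not say how each sample relates to a separate animal beyond the stated number of mice, p-values measure the spread between these samples.

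From these files, log2 of the processed intensity minus the array's 75th percentile was computed, spots of one probe were averaged, and probes were kept if well above background on all 3 arrays of at least 1 group, which left 31720 of 56605 probes. The probe with the highest mean represented each gene, giving 20737 genes tested. Probes were named through the reference gene table of the GRCm38.p6 assembly: 32994 probes matched by accession, 10224 by symbol and 520 by an older symbol, and 12867 kept the name in the file. Probe coordinates are those of the files, on the mm9 build. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on group alone, two-sided, Benjamini-Hochberg over genes, threshold 0.05). For a probe that was not well above background on any array of one group, a fold is given as a lower bound, from the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Simulated data held the same 20737 genes, drawn independently of each other, with 200 changed genes in each of 20 draws. On them the test recovered 32.2% of genes changed 2-fold, 85.7% of those changed 4-fold and 94.6% of those changed 8-fold. Of its calls 5.8% were false. Genes on the real arrays vary together, so these rates need not hold there.

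Before the data were examined, 49 gene lists with 1128 entries were fixed, of which 48 had the 5 measured members a test needed. They cover FGF signalling, proliferation, bile duct identity, mucins, gastric, intestinal and other epithelial programmes, signalling pathways, inflammation, markers of other cell types, stress and metabolism. Lists were tested with limma's camera, a competitive test of a list against all other measured genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were alternatives. In 20 simulated draws with no changed list, camera with the preset correlation called 0.1 of 48 lists on average when genes varied independently. When the members of each list shared a random array-wide factor, it called 25.15 lists on average, and camera with an estimated correlation called 0. Calls with the preset correlation therefore do not account for genes of a list that vary together between samples.

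The rule for named genes was also fixed beforehand. It takes Fgf10 and Fgfr1 to Fgfr4. Among genes past the threshold whose groups do not overlap, it takes up to 10 in each direction that were well above background on all 6 arrays, and up to 4 in each direction that were not above background in one group. It takes up to 4 measured members of each list with the smallest p. Clone, accession and placeholder names were excluded from the genes past the threshold. Of the list members the rule takes, those of lists past the threshold and of lists close to the study's question are named here. Genes chosen after their values were seen are marked as such.

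Alternatives were quantile normalisation, scaling to the median, normexp background correction of the raw signals with an offset of 50, the authors' processed values, no filter on dim probes, a filter on all 6 arrays, every probe or the mean of a gene's probes, eBayes with trend or robust (with statmod 1.5.0), array weights, the replicate number as a block, the slide row as a block, and each array left out in turn. Leaving out DOX- replicate 3 and DOX+ replicate 3 was also asked for after the data were seen, and both were already planned. Nothing in the protocols used here states that replicate numbers pair the samples.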

Results

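The data comprise 6 arrays of bile duct epithelium, 3 from iFGF10 mice given doxycycline (DOX+) and 3 from mice given water (DOX-). FGF10 is a secreted fibroblast growth factor that signals mainly through the receptor FGFR2 in epithelia. The series title names papillary neoplasia of the biliary tree and FGF10 signalling, so the comparison asks which genes differ in the duct epithelium after 5 days of induction. Between 55.93% and 61.9% of spots were well above background on each array. The smooth muscle marker Acta2 was well above background on all 6 arrays, with mean log2 levels of 5.46 in DOX+ and 5.1 in DOX-. The fibroblast gene Col1a1 was as well, at 2.97 and 3.78. The samples thus held RNA of other cell types too, and a difference between the groups need not lie within epithelial cells. The correlation between arrays across genes, which are not independent replicates, was 0.971 to 0.98 within DOX+, 0.964 to 0.985 within DOX- and 0.954 to 0.973 between the groups. The first principal component, with 41.56% of the variance, placed all 3 DOX+ arrays on one side of the 3 DOX- arrays. Positions on it were -22.61, -50.9 and -37.73 for DOX+ and 3.64, 36.13 and 71.47 for DOX- (replicates 1 to 3). DOX- replicate 1, in the slide row of the DOX+ arrays, thus lay nearer to each of them than to DOX- replicate 3.

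Fgf10 itself was not well above background on any of the 6 arrays. Its 3 probes lie on chromosome 13 (mm9), between 119568951 and 119580424. Their log2 levels in DOX+ and DOX- were -7.27 ± 0.14 and -7.09 ± 0.18 for the probe at 119568951, -6.76 ± 0.31 and -6.90 ± 0.20 for that at 119577931, and -6.51 ± 0.86 and -7.04 ± 0.18 for that at 119580365 (SD, n = 3 each). Whether any probe matches the induced transcript is not known, because the sequence of the construct is not given in the sources used here, so these probes do not check the labels. Among the receptors, the probes used for Fgfr1, Fgfr2, Fgfr3 and Fgfr4 were well above background on all arrays. Their log2 differences, DOX+ minus DOX-, were 0.46 ± 0.51 for Fgfr1, 0.58 ± 0.28 for Fgfr2, 0.56 ± 0.26 for Fgfr3 and 1.33 ± 0.34 for Fgfr4 (SE), and none passed the limma test (adjusted p = 0.731, 0.430, 0.404 and 0.233). With the slide row as a block the difference of Fgfr1 was -0.31.

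**Figure D1:**
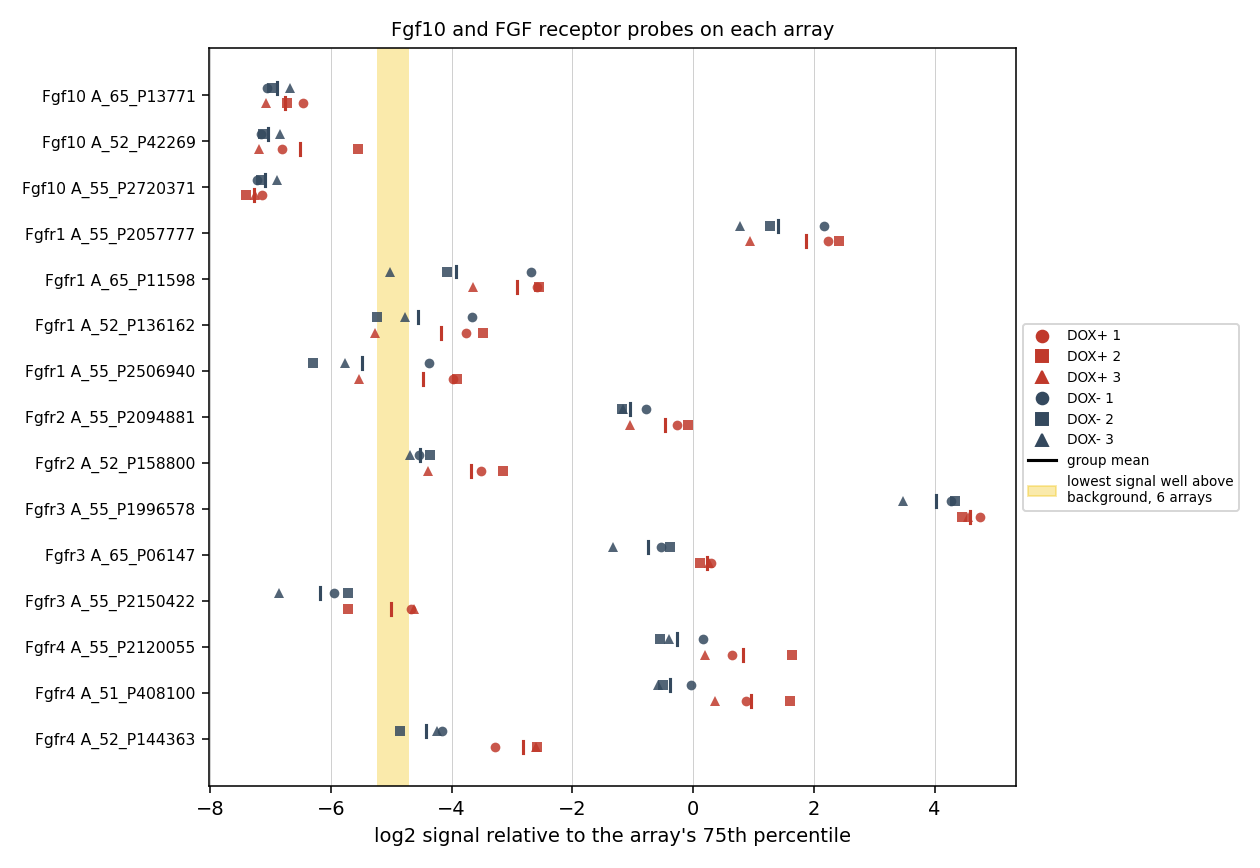
Log2 signal of each Fgf10 and FGF receptor probe relative to the 75th percentile of its array (horizontal axis), with 1 point per array, DOX+ in red and DOX- in dark blue, and short bars for group means. The yellow band spans the lowest signals well above background on the 6 arrays, from -5.23 to -4.71, and all Fgf10 points lie to its left.

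In the DOX+ samples 8 of 20737 genes passed the test, 4 higher and 4 lower, and all 8 differed at least 2-fold. Rab6b, a small GTPase of Golgi transport, fell by 3.48 on the log2 scale, from 0.11 ± 0.40 in DOX- to -3.37 ± 0.05 in DOX+ (SD, n = 3; limma adjusted p = 0.0246). Hspa1b, an inducible HSP70 heat shock chaperone, fell by 1.84 (SE 0.12; limma adjusted p = 0.0246), and Itgb6, the epithelial integrin beta 6 subunit, fell by 1.81 (SE 0.15; limma adjusted p = 0.0479). Cstdc1, a gene with a cystatin-like domain, rose from a signal not well above background on any DOX- array to -2.87 ± 0.22 in DOX+, at least 4.11-fold (limma adjusted p = 0.0425). All 4 genes had the 3 DOX+ arrays on one side of the 3 DOX- arrays, which the rule for named genes required.

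The probes used lie on mm9 at chromosome 9, 103087539 to 103087598, for Rab6b, at chromosome 17, 35093374 to 35093405, for Hspa1b, at chromosome 2, 60438632 to 60443247, for Itgb6, and at chromosome 2, 148611612 to 148611671, for Cstdc1. A second Itgb6 probe, well above background on 2 of 3 DOX+ arrays, gave a difference of -1.92. A second Cstdc1 probe, at 148611585 to 148611644, was not well above background in either group. It overlaps the first Cstdc1 probe, and the sequences differ by a base in the shared stretch, so a sequence variant stays open for Cstdc1. Hspa1a, a near-identical copy of Hspa1b, had a log2 difference of -1.60 (limma adjusted p = 0.0922), and which of the copies gave the signal is uncertain.

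The other 4 genes past the test have placeholder names and were named after their values were seen. AA465934, at chromosome 11, 83105324 to 83105516, rose by 3.70 (SE 0.18), from -2.85 ± 0.13 to 0.85 ± 0.29 (SD, n = 3), with the smallest adjusted p of all genes (limma, 0.0135). Its second probe, at 83105675 to 83105734, was not well above background on any array. The transcript ENSMUST00000103521, at chromosome 12, 116358101 to 116358160, and ENSMUST00000137124, at chromosome 11, 57877383 to 57877442, were not well above background on any DOX- array and were at least 3.49-fold and 1.54-fold higher in DOX+ (limma adjusted p = 0.0384 each). A long noncoding RNA probe at chromosome 3, 65729719 to 65729778, fell by 1.73 (limma adjusted p = 0.0384). Itgb8, the integrin beta 8 subunit, also chosen after its values were seen, missed the threshold with a log2 difference of 1.85 (SE 0.17; limma adjusted p = 0.0596). Of its 4 probes, 3 had signal well above background in both groups, 1 of them on 2 of 3 DOX- arrays, and gave differences between 1.72 and 2.15.

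**Figure D2:**
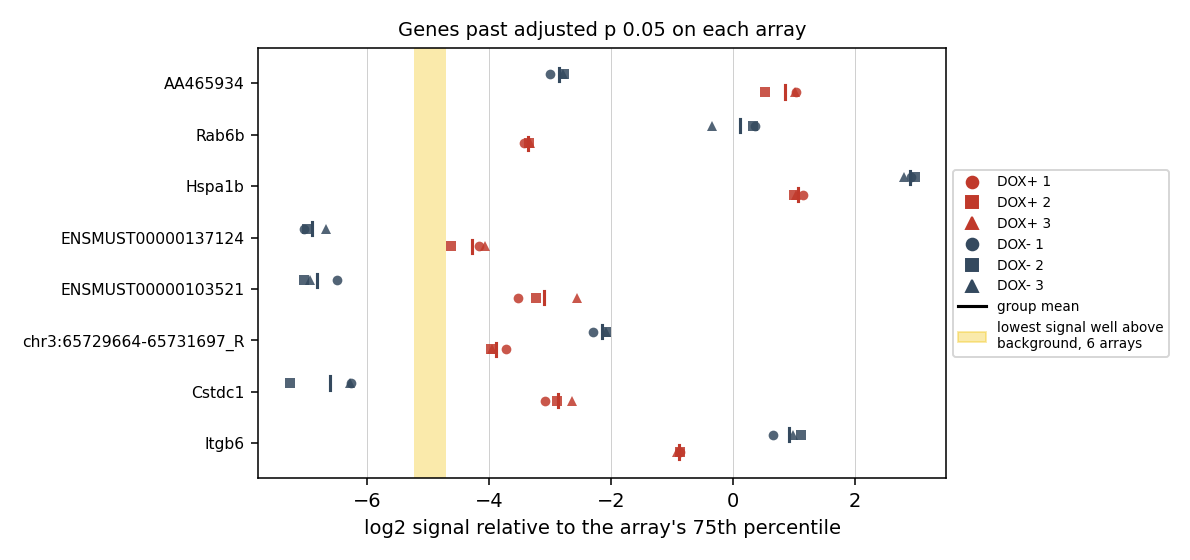
Log2 signal of the 8 genes past the test relative to the 75th percentile of each array (horizontal axis), with 1 point per array, DOX+ in red and DOX- in dark blue, and short bars for group means. The yellow band spans the lowest signals well above background on the 6 arrays, and in each of the 8 genes the 3 DOX+ points lie apart from the 3 DOX- points.

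Of all 20737 genes, the 8 included, 2766 had an unadjusted p under 0.05 where chance would give 1037, and 4355 (21%) had groups that did not overlap where chance gives 10%. Other divisions of the 6 arrays gave 189 to 2100 genes at that p. The genes that passed changed when an array other than DOX- replicate 2 was left out, with 3 to 5 of the 8 among them. Their directions changed too, with 24 higher and 6 lower without DOX+ replicate 1, but 3 higher and 16 lower without DOX- replicate 3. The count of 8 rests on few arrays: without DOX- replicate 2 no gene passed the limma test, with 1555 at an unadjusted p under 0.05, and without the other arrays 10 to 30 genes passed. It was 2 with the authors' processed values, 0 with the slide row as a block (1409 at an unadjusted p under 0.05), which sets the DOX+ arrays against DOX- replicate 1 alone, and 259 with array weights, which gave DOX- replicate 2 a weight of 4.03.

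Genes that respond to FGF signalling through MAPK did not move together. Of 23 measured members 10 were higher and 13 lower in DOX+, with a median log2 difference of -0.07 (camera adjusted p = 0.624, direction down). Without single arrays the median lay between -0.13 and 0.03. Adjusted over the list alone, 1 member was higher and 1 lower, and over all genes 0 passed. The 2 ETS transcription factors Etv1 and Etv5, targets of FGF signalling in many tissues, had differences of 1.84 (SE 0.40) and 0.76 (SE 0.25), while Phlda1 and the immediate early gene Fos had differences of -1.27 (SE 0.19) and -1.23 (SE 0.42). The list of FGF ligands and receptors rose, with 11 of 14 measured members higher and a median of 0.53 (camera adjusted p = 0.00238; adjusted p = 0.782 with an estimated correlation). Its array means overlapped between the groups (shift 0.49 ± 0.29, SE, n = 3; two-sided exact permutation p = 0.2). Its members with the smallest p after Fgfr4 were Frs3, an adaptor of FGF receptors (0.50), the co-receptor Klb (0.90, well above background on 1 of 3 DOX- arrays) and Fgf1 (0.93), and 0 members passed over all genes or adjusted over the list alone. Without DOX+ replicate 2 that list's adjusted p was 0.110. EGF receptor ligands and receptors did not pass (median -0.10, camera adjusted p = 0.175), with 1 member lower adjusted over the list alone. Their array means did not overlap (shift -0.19 ± 0.06, SE, n = 3; two-sided exact permutation p = 0.1). Without single arrays the median ran from -0.24 to -0.04. Differences were -1.004 for Hbegf, -0.70 for Btc, -0.52 for Egfr and 0.84 for Egf.

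Both lists of proliferation genes fell in the DOX+ samples with the preset correlation. All 31 measured genes of G1/S and DNA replication had lower means, with a median log2 difference of -0.74 (camera adjusted p = 1.86e-09; adjusted p = 0.782 with an estimated correlation). Of the 30 measured genes of G2/M and mitosis 29 had lower means, with a median of -1.25 (camera adjusted p = 5.72e-10; adjusted p = 0.782 with an estimated correlation). No single member passed, over all genes or adjusted over its list alone, and 13 and 15 members of the 2 lists had an unadjusted p under 0.05. Differences were -1.37 (SE 0.33) for E2f2, a transcription factor of S phase entry, -1.04 (SE 0.30) for Mcm10 and -0.75 (SE 0.24) for Cdt1, both replication factors, and Cdc45, of the replicative helicase, was at least 1.51-fold lower and not well above background on any DOX+ array. Among mitotic genes they were -1.26 (SE 0.29) for the checkpoint kinase Bub1b, -1.55 (SE 0.50) for the spindle factor Tpx2, -1.41 (SE 0.46) for Ect2 and -0.67 (SE 0.19) for Incenp. Bub1b and Tpx2 were well above background on 2 of 3 DOX+ arrays. The groups were not separated at the level of arrays: the mean shift was -0.73 ± 0.31 for G1/S and -1.22 ± 0.59 for G2/M (SE, n = 3 each), with a two-sided exact permutation p of 0.2 for each, where 0.1 is the smallest p that 3 against 3 can give.

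Cholangiocyte markers fell as a list. Of 27 measured members 22 were lower and 5 higher, with a median of -0.27 (camera adjusted p = 0.0019; adjusted p = 0.782 with an estimated correlation), and the array means of the groups did not overlap (shift -0.29 ± 0.05, SE, n = 3; exact permutation p = 0.1). Over all genes 0 members passed, and adjusted over the list alone 5 were lower and 1 higher. The differences were -2.01 (SE 0.37) for Cdh1, which encodes E-cadherin, -1.02 (SE 0.19) for the ductal keratin Krt7 and -1.75 (SE 0.31) for the bile acid transporter Slc10a2, against 1.73 (SE 0.24) for the glucose transporter Slc5a1. Slc5a1 was well above background on 1 of 3 DOX- arrays. Beside these shifts, mast cell and eosinophil markers and endothelial markers were higher in DOX+ with the preset correlation (adjusted p = 0.782 for each with an estimated correlation), with array means that overlapped between the groups for the endothelial list. Macrophage, fibroblast and smooth muscle markers did not pass. Macrophage markers passed as lower without DOX- replicate 3 (camera adjusted p = 1.42e-05). Fibroblast and smooth muscle markers passed as higher without DOX- replicate 1 (0.0335 and 2.22e-06) and as lower with the slide row as a block (0.000511 and 2.59e-13; medians -0.45 and -1.18).

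Mucin and mucus secretion genes did not shift as a list. Of 28 measured members 17 were higher and 11 lower, with a median of 0.18 (camera adjusted p = 0.703), although the array means did not overlap (shift 0.53 ± 0.21, SE, n = 3; exact permutation p = 0.1). Without DOX+ replicate 2 the median was 0.02. Adjusted over the list alone, 2 members were higher and 2 lower, and 0 passed over all genes. Agr2, a protein disulfide isomerase needed for mucin folding, had a difference of 5.56 (SE 1.07; limma adjusted p = 0.176), and Creb3l1 0.95 (SE 0.23). The membrane mucin Muc4 had -1.21 (SE 0.19) and Galnt3, which starts mucin glycosylation, -1.02 (SE 0.23).

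Markers of mast cells and eosinophils rose as a list, with 12 of 14 measured members higher and a median of 1.94 (camera adjusted p = 7.41e-05; adjusted p = 0.782 with an estimated correlation). The array means did not overlap (shift 1.83 ± 0.80, SE, n = 3; exact permutation p = 0.1). Adjusted over the list alone 7 members were higher, and over all genes 0 passed. Differences were 5.57 (SE 1.498) for the mucosal mast cell protease Mcpt1, 3.41 (SE 0.82) for the IgE receptor subunit Fcer1a, 2.18 (SE 0.42) for the tryptase Tpsb2 and 2.17 (SE 0.61) for Cpa3. Fcer1a was well above background on 1 of 3 DOX- arrays. Endothelial markers also rose, with 18 of 19 higher, a median of 0.47 and 4 higher adjusted over the list alone (camera adjusted p = 1.32e-05; adjusted p = 0.782 with an estimated correlation). Their array means overlapped between the groups (shift 0.54 ± 0.22, SE, n = 3; exact permutation p = 0.2). Their differences were 0.73 for Plvap, 0.66 for Tie1, 0.54 for Pecam1 and 1.94 for Vwf.

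**Figure D3:**
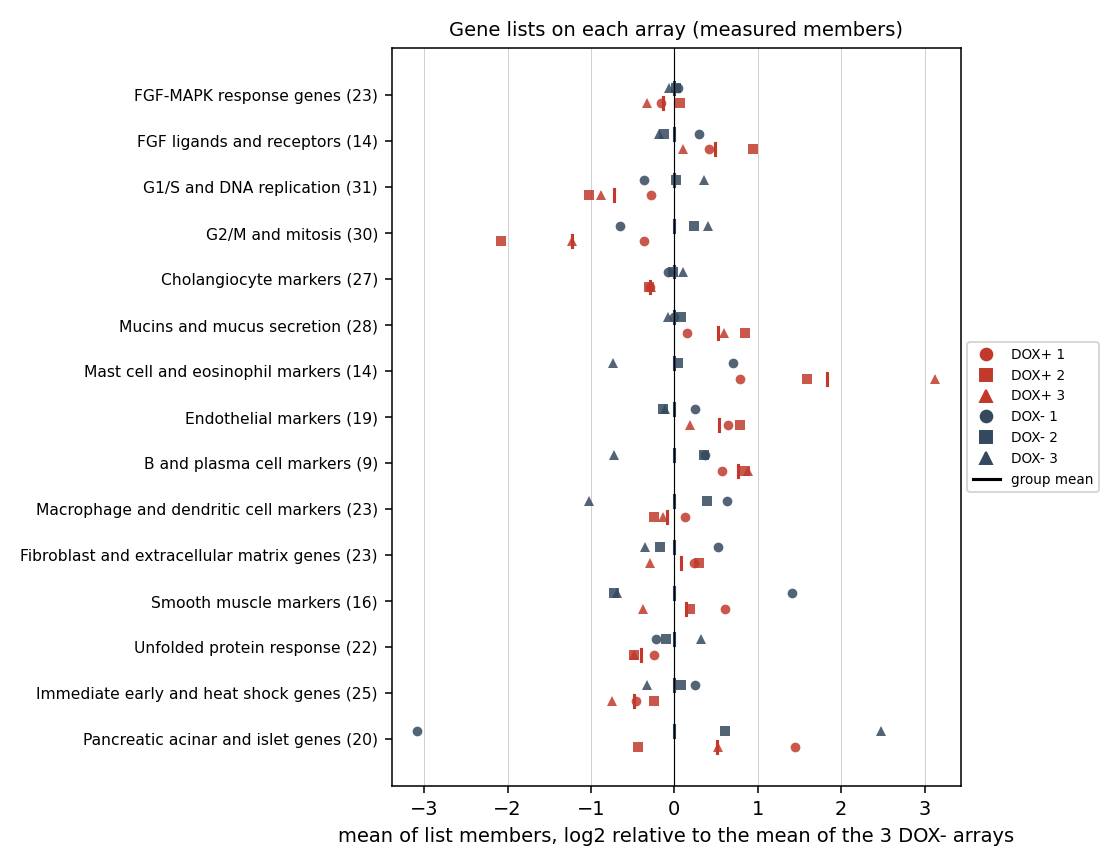
Mean log2 level of the measured members of 15 gene lists on each array, relative to the mean of the 3 DOX- arrays (horizontal axis), with 1 point per array, DOX+ in red, DOX- in dark blue, short bars for group means and the number of measured members in brackets. The DOX+ points for cholangiocyte markers all lie below the DOX- points, those for mast cell and eosinophil markers all lie above, and the pancreatic list spreads more between DOX- arrays than between groups.

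Of 25 immediate early and heat shock genes 18 were lower with a median of -0.44 (camera adjusted p = 0.00238; adjusted p = 0.782 with an estimated correlation), and 3 were lower adjusted over the list alone. Beside Hspa1b the differences were -0.64 for Dnajb1 and -1.09 for Hsph1, both chaperones. Of 22 unfolded protein response genes 21 were lower with a median of -0.40 (camera adjusted p = 1.83e-05; adjusted p = 0.822 with an estimated correlation), among them Pdia6 (-0.67) and Sdf2l1 (-1.43). Of 26 cholesterol and fatty acid synthesis genes 24 were lower with a median of -0.56 (camera adjusted p = 0.0019; adjusted p = 0.923 with an estimated correlation), among them Elovl6 (-0.78). Of 26 ribosome biogenesis and MYC target genes 22 were lower with a median of -0.22 (camera adjusted p = 0.000369; adjusted p = 0.822 with an estimated correlation), among them Fbl (-0.54) and Nop58 (-0.65). In the last 3 lists 0 members passed over all genes or adjusted over the list alone. The array means of the groups overlapped for the immediate early and heat shock list (shift -0.49 ± 0.23; two-sided exact permutation p = 0.2) and the cholesterol and fatty acid list (-0.46 ± 0.32, SE, n = 3 each; p = 0.3). They did not overlap for the other 2 (exact permutation p = 0.1 each). Without DOX- replicate 1 the median of the immediate early and heat shock list was -0.065 (camera adjusted p = 0.063). Without DOX- replicate 3 the medians were -0.24 for cholesterol and fatty acid synthesis (camera adjusted p = 0.101), -0.25 for the unfolded protein response and -0.13 for ribosome biogenesis. Both of the latter still passed.

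In all, 10 of the 48 lists tested passed with the preset correlation, 3 higher and 7 lower, and 0 passed with an estimated correlation or with fry. The adjusted p of 0.782 came from the adjustment over lists and covers unlike lists. Before adjustment, camera with an estimated correlation gave p = 0.0546 for cholangiocyte markers (correlation 0.048) and 0.195 for G2/M (0.816). The simulations held no changed list, so how often this version misses a real shift is not known. With the slide row as a block, which sets the DOX+ arrays against DOX- replicate 1 alone, 4 of the 10 no longer passed: FGF ligands and receptors (camera adjusted p = 0.27), the unfolded protein response (0.0557), cholesterol and fatty acid synthesis (0.627) and ribosome biogenesis (0.0577). Among the other 6, medians moved to -0.31 for G1/S, -0.55 for G2/M, 0.83 for mast cell and eosinophil markers and 0.25 for endothelial markers. Shifts of their array means under that block were -0.36 (SE 0.4), -0.58 (SE 0.81), 1.13 (SE 1.18) and 0.29 (SE 0.29). Those of cholangiocyte markers and of immediate early and heat shock genes were -0.21 (SE 0.06) and -0.74 (SE 0.31).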

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

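The tests of the FGF-MAPK list against blind probes, of the 3 explanations for the mast cell list, of genes with 1 measured probe and of neighbours within 100 kb were chosen only after the result was seen.

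Outside the tested genes, 356 genes left out by the filter had a probe well above background on 2 of 3 DOX+ arrays and on no DOX- array, against 155 genes the other way round. They were picked out because this signal lies in probes the comparison does not use and exceeds the count in the control direction. DOX- replicate 3 had the lowest share of spots well above background, 55.93% against 59.39% to 61.9% on the other 5 arrays.

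Fgf10 was not well above background on any array although the DOX+ mice are described as overexpressing it. Background subtraction by the authors is argued against: the raw signals of its 3 probes exceeded the 99th percentile of the 308 negative control spots in 0 of 18 probe and array pairs. Raw signals were 70.61 to 92.5 in DOX+ against limits of 96.16 to 109.68, and 70.15 to 79.07 in DOX- against limits of 99.6 to 114.74. Whether the probes miss the induced transcript while the ligand acts on these cells cannot be told apart from no effect on the FGF-MAPK list, which went neither way (camera adjusted p = 0.6241). Expression in cells that were not sampled remains an open biological explanation and was not tested.

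A few genes differed strongly with little spread, AA465934 and Rab6b above all, and the control samples carry names that begin with WT, so a difference in genotype is a possible explanation beside induction. A sequence variant under single probes is argued against only as the cause across the 26 that had a further measured probe among 91 genes with an unadjusted p under 0.001 (genes with a symbol, and AA465934; the other placeholder names were not tested), where the other probes showed a median 1.01 of the change (bootstrap 95% interval 0.822 to 1.108). It stays open for 3 of these 26, Cuedc1, Lypd6b and Raver2, named after their values were seen. In these 3 the other probe showed 0.302, 0.229 and 0.026 of the change. It also stays open for the other 65, AA465934, Rab6b and Cstdc1 among them. The median difference of the 65 was 0.28 larger in size than that of the 26 (-0.12 to 0.55). A chromosome segment that differs between the groups cannot be told apart from induction: 23 pairs lay within 5 Mb on mm9, not counting 3 whose names share their first 4 letters, against a random median of 24 under the same rule, which meets the bound set beforehand for arguing against it, but not by more than the spread of the random sets (5th and 95th percentiles 16 and 35), and that need for a margin was added after the value was seen. Scpep1 and Elobl, neighbours on chromosome 11 noticed after the values were seen, are the 1 pair counted within 100 kb. Hspa1a with Hspa1b and Hoxb6 with Hoxb7 were left out for their shared letters. A share of 0.6117 of random sets held as many counted pairs, so chance can account for a pair this close. Such counts over all genes cannot decide on a segment at 1 place. Also within 5 Mb on chromosome 11 lay AA465934 with Cuedc1, and Cuedc1 with Scpep1 and Elobl, all higher in DOX+.

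Mast cell and eosinophil markers were higher in DOX+ as a list with the preset correlation, but not past the threshold with an estimated correlation (adjusted p = 0.782) or with fry (0.376). A lower share of epithelium, which would raise every other cell type alike, stays open. The mast cell shift was 1.92 (SE 0.78) larger than that of macrophage and dendritic cell markers, which goes against it. That gap rests on 3 arrays per group, and the DOX+ array means of the mast cell list ran from 0.78 to 3.12. The DOX- array means of the macrophage list had an SD of 0.89. Cholangiocyte markers fell while endothelial markers rose, as a lower share would give, so the gap cannot decide. Position on the slide cannot be told apart from the group: DOX- replicate 1, in the row of the DOX+ arrays, had a list mean that differed from the lowest DOX+ mean by -0.08 (SD of the DOX- arrays 0.72), and with the slide row as a block the list still passed with the preset correlation (camera adjusted p = 0.00837), but its shift, which then rests on that 1 control, was 1.13 (SE 1.18). RNA from another slice of the duct wall is likewise open, since fibroblast and smooth muscle markers shifted by 0.11 (SE 0.53). More mast cells in or near the epithelium after induction, or in response to doxycycline, may explain the shift as a hypothesis, and the design does not separate these.

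With 3 against 3 arrays there are 10 divisions, too few for a share under 0.05. The real division gave 8 genes past adjusted p, and the highest of the other 9 was 0 (1 of 10 as large); the same 8 genes were at least 2-fold, again with 0 elsewhere (1 of 10). At an unadjusted p under 0.05 limma gave 2766 genes for the real division and 189 to 2100 for the others, with the filter on dim probes set on the real groups throughout. For gene lists the real count was 10 and the highest of the others 24, and all 10 of 10 divisions gave at least as many, so the number of lists points to genes that vary together between the samples whatever the grouping. The division of DOX+ replicate 1 with DOX- replicates 1 and 2 gave the 24 lists.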

How the results depend on the processing

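No alternative here was chosen only after seeing the data. The 8 genes past the test kept their direction under all alternatives that measured them, but their number varied: at adjusted p under 0.05 it was 2 with quantile normalisation, 5 with scaling to the median (which put the median log2 difference of all genes at -0.113, against -0.012), 2 with the authors' processed values, 1 without a filter on dim probes, 5 with the filter on all 6 arrays, 18 with every probe tested (here more tests were run per gene), 259 with array weights, 0 with the slide row as a block, 7 to 11 with normexp, the mean of a gene's probes and eBayes with trend or robust, and 0 to 30 when single arrays were left out. At least 2-fold the counts were 2, 5, 2, 1, 5, 18, 194 and 0 up to the slide row, and 0 to 30 with single arrays left out. With the replicate block 0 genes passed (2258 at an unadjusted p under 0.05, limma), in either count. Same-numbered arrays deviated with correlations of -0.087, -0.131 and -0.02, against -0.129 to 0.219 for arrays of unlike number. This gives no sign that the numbers pair the samples, but 3 arrays per group cannot exclude it. AA465934 passed in 16 of 19 alternatives, Rab6b in 15, Hspa1b in 11 and Itgb6 in 8. The chromosome 3 probe passed in 6 of 19, ENSMUST00000103521 in 8 of 18, and ENSMUST00000137124 and Cstdc1 in 6 of 18 each. Across alternatives the log2 difference was as low as 1.29 for Cstdc1, 1.16 for ENSMUST00000103521 and 0.66 for ENSMUST00000137124. The lower bounds of fold given above hold for the main processing alone. The difference of the Fgf10 probe at 119577931, between signals not well above background, stayed within the spread of the arrays in all alternatives. Gene lists past the threshold numbered 0 with an estimated correlation, 0 with fry, 16 without a filter, 19 with the slide row as a block and 12 to 19 when single arrays were left out. With an estimated correlation adjusted p was 0.782 for G1/S, G2/M and cholangiocyte lists, and with fry 0.376, 0.383 and 0.121. The slide row as a block gave 0.27 for FGF ligands and receptors, 0.0557 for the unfolded protein response, 0.627 for cholesterol and 0.0577 for ribosome biogenesis. With the slide row as a block the difference rests on DOX- replicate 1, the one control in the row of the DOX+ arrays, so fewer samples enter it, as when arrays are left out. The cause was not tested for the others. Signal over background limits dim genes: 148 higher and 24 lower genes were not well above background in one group.

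Lists that had not passed turned direction as follows, with adjusted p. Fry turned bile acid (0.996), erythrocyte (0.996) and amino acid (0.996). Quantile normalisation turned bile acid (0.904), prostaglandin (0.896), macrophage (0.993) and mitochondrial (0.807). Scaling to the median turned bile acid (0.865), Wnt (0.796), prostaglandin (0.981) and macrophage (0.861). Normexp turned bile acid (0.951), cilium (0.951), Wnt (0.999), prostaglandin (0.951) and macrophage (0.972). The authors' processed values turned bile acid (0.904), prostaglandin (0.895), macrophage (0.993) and mitochondrial (0.803). No filter on dim probes turned peribiliary (0.891), bile acid (0.517), cilium (0.641), Wnt (0.891), prostaglandin (0.89) and macrophage (0.479). The filter on all 6 arrays turned intestinal (0.965), bile acid (0.986), cilium (0.936), macrophage (0.936) and B cell (0.979). The mean of a gene's probes turned cilium (0.838), prostaglandin (0.695) and erythrocyte (0.974). Array weights turned bile acid (0.816), Wnt (0.978), prostaglandin (0.978) and antigen presentation (0.798). The replicate block turned erythrocyte (0.982). The slide row as a block turned bile acid (0.605), Notch (0.813), Hedgehog (0.602), antigen presentation (0.27), T cell (0.789), fibroblast (0.000511), smooth muscle (2.59e-13), adipocyte (0.959), amino acid (0.926) and mitochondrial (0.067). The Fgfr1 difference turned to -0.31 with the slide row as a block. Leaving out single arrays turned antigen presentation (0.063 to 0.658 over the 6 arrays), bile acid (0.37 to 0.824), mesenchymal transition (0.053 to 0.71), erythrocyte (0.0429 to 0.88), fibroblast (0.0335 to 0.78), gastric (0.178 to 0.922), hepatocyte (0.0115 to 0.677), hypoxia (0.0939 to 0.699), interferon (0.0778 to 0.93), intestinal (0.015 to 0.699), macrophage (1.42e-05 to 0.922), mitochondrial (0.0309 to 0.751), Notch (0.0358 to 0.801), pancreatic (0.000936 to 0.62), peribiliary (0.473 to 0.845), cilium (0.266 to 0.76), prostaglandin (0.655 to 0.999), smooth muscle (2.22e-06 to 0.751), keratin (0.198 to 0.984), T cell (0.0062 to 0.959), TGF-beta (0.0429 to 0.59), tuft cell (4.8e-05 to 0.502) and Wnt (0.293 to 0.905) lists at least once; of the turned values 1 passed, that of the pancreatic list without DOX- replicate 1 (0.0493). With the slide row as a block the turned fibroblast and smooth muscle lists passed. Apart from that block and the left-out arrays, the cause was not tested. Among single genes named, 1509 comparisons with an alternative kept direction and side of the threshold, 33 came to pass, 73 no longer passed and 1 turned.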

Other observations

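The test of plasma cell genes was chosen only after the result was seen, and single genes outside the fixed lists were chosen after their values were seen.

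Of 18 measured chemokines and inflammatory cytokines 14 were lower in DOX+, with a median of -0.58 (camera adjusted p = 0.053), and adjusted over the list alone 2 were lower and 1 higher. This list passed in 10 of 21 alternatives, among them without DOX+ replicate 1 or 2 (0.0477 and 0.0459) and without DOX- replicate 3 (8.03e-05, median -0.98), while the median was -0.30 without DOX+ replicate 3 and the adjusted p 0.868 with an estimated correlation. Differences were -2.32 for Ccl20 and -1.32 for Cxcl16, both epithelial chemokines, -4.70 for the neutrophil attractant Cxcl5 and 2.81 for Ccl8. Antimicrobial genes had a median of -0.10 (camera adjusted p = 0.490), with Reg3g, an antibacterial lectin, at -4.32 (SE 1.11; limma adjusted p = 0.236). Neutrophil markers (median -0.20, camera adjusted p = 0.642), macrophage and dendritic cell markers (-0.08, 0.982) and interferon response genes (0.01, 0.593) did not pass, and Cd163, a macrophage scavenger receptor, had a difference of 1.38. Markers of T and NK cells (median 0.39, camera adjusted p = 0.0768), B and plasma cells (0.33, 0.256) and antigen presentation (0.13, 0.472) had higher medians and did not pass. Without DOX- replicate 3, antimicrobial (camera adjusted p = 0.00948), neutrophil (0.00455) and macrophage (1.42e-05) lists passed as lower, as did the antimicrobial list without DOX+ replicate 3 (0.0352). The T and NK cell list passed as higher without DOX- replicate 1 or 2 (0.0062 and 0.0179), but turned without DOX- replicate 3 (median -0.02, adjusted p = 0.959) and with the slide row as a block (median -0.045). The macrophage list turned without DOX+ replicate 2 or 3 or DOX- replicate 1 or 2 (adjusted p = 0.751, 0.922, 0.109 and 0.486), and antigen presentation without DOX- replicate 3 (0.13).

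Of 20 measured p53 targets and cell cycle inhibitors, 4 were lower and 1 higher adjusted over the list alone (median -0.13, camera adjusted p = 0.144), with differences of -1.45 for Pmaip1, -0.84 for Phlda3 and -2.37 for the cell cycle inhibitor Cdkn2b. Of 25 xenobiotic and glutathione genes, 3 were higher and 1 lower adjusted over the list alone (median 0.20, camera adjusted p = 0.126), with 1.03 for Gstm3, 2.31 for the quinone reductase Nqo1 and -1.68 for Cyp4b1. In the amino acid response list (median 0.07, camera adjusted p = 0.703) the cystine transporter Slc7a11 was lower adjusted over the list alone, at least 4.29-fold and not well above background on any DOX+ array (limma adjusted p = 0.103). In the Notch list (median 0.08, camera adjusted p = 0.175) 1 member was higher adjusted over the list alone, and the ligand Jag2 and receptor Notch3 had differences of 0.93 and 0.75. Among 22 intestinal genes 2 were higher adjusted over the list alone (median 0.34, camera adjusted p = 0.642), with 1.69 for the peptidase Anpep, and among 25 bile acid and ion transport genes (median -0.002, camera adjusted p = 0.921) 1 was higher and 1 lower, with 1.59 for Slc26a3, a chloride and bicarbonate exchanger. Of 22 genes of epithelial-mesenchymal transition (median -0.003, camera adjusted p = 0.703) Itgb6 alone passed over all genes and adjusted over the list alone. In the neuroendocrine list (median 0.21, camera adjusted p = 0.126) Tph1, which makes serotonin also in mast cells, was at least 5.96-fold higher and not well above background on any DOX- array (limma adjusted p = 0.236). Intestinal and neuroendocrine lists passed as higher without DOX+ replicate 1 (camera adjusted p = 0.015 and 0.00526), the Notch list without DOX- replicate 1 (0.0358), and the xenobiotic list without DOX+ replicate 2 (0.0379) or DOX- replicate 3 (0.047). The intestinal list turned without DOX+ replicate 3 (adjusted p = 0.511; median 0.008) and the Notch list without DOX- replicate 3 (0.801; median 0.012).

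The remaining lists did not pass with camera on all 6 arrays, and 0 of their members passed over all genes or adjusted over the list alone. Epithelial lists had medians of 0.21 for gastric genes (adjusted p = 0.593), -0.48 for tuft cells (0.344), -0.10 for squamous and basal keratins (0.593), -0.04 for peribiliary gland and foregut progenitors (0.811) and -0.02 for primary cilium genes (0.982). Signalling lists had medians of -0.24 for Hippo-YAP targets (adjusted p = 0.066), 0.39 for Hedgehog (0.18), -0.12 for TGF-beta and BMP (0.535), -0.005 for Wnt (0.921) and 0.05 for prostaglandin and hyaluronan synthesis (0.921). Other cell types had medians of 0.07 for fibroblasts (adjusted p = 0.856), 0.15 for smooth muscle (0.703), -0.22 for neurons and glia (0.642), -0.24 for hepatocytes (0.593), 0.90 for pancreas (0.535), 0.69 for adipocytes and mesothelium (0.285) and -0.09 for erythrocytes (0.921). Mitochondrial genes had a median of -0.07 (adjusted p = 0.465) and hypoxia and glycolysis genes 0.03 (0.473). Camera's direction was up for erythrocytes and the amino acid list and down for Wnt, prostaglandin and interferon genes, where the median, the mean and the test differ in sign. The sex-linked list had 4 measured members, too few to test, with a median of 0.09. Pancreatic genes spread widely within DOX-, with an SD of 2.82 between array means against 0.95 in DOX+. Of the 38 lists that did not pass, 19 did without some single array. Among those of this paragraph, by array left out, tuft cell (lower, camera adjusted p = 4.8e-05), Hedgehog (higher, 0.0258) and mitochondrial genes (lower, 0.0328) passed without DOX+ replicate 3. Hedgehog (higher, 0.00684), fibroblast (higher, 0.0335), smooth muscle (higher, 2.22e-06), pancreatic (lower, 0.0493) and mitochondrial genes (lower, 0.0309) passed without DOX- replicate 1. TGF-beta (lower, 0.0429), hepatocyte (lower, 0.0115), pancreatic (higher, 0.000936) and erythrocyte genes (higher, 0.0429) passed without DOX- replicate 3. Hepatocyte genes also passed as lower without DOX+ replicate 2 (0.0349), and Hippo-YAP targets without DOX+ replicate 1 or 2 or DOX- replicate 2 or 3 (0.00145 to 0.042). Across left-out arrays the Hippo-YAP median came as near 0 as -0.11, and its camera adjusted p reached 0.699. Leaving out another array turned some of these lists, with medians of 0.12 for tuft cells without DOX+ replicate 1, 0.11 for mitochondrial genes without DOX- replicate 3 and 0.11 for TGF-beta without DOX- replicate 1. Hepatocyte genes turned without DOX+ replicate 1 or DOX- replicate 1 (0.38 and 0.32). Fibroblast and smooth muscle lists turned without DOX+ replicate 1 or DOX- replicate 2 or 3, the fibroblast list also without DOX+ replicate 2, and erythrocyte genes without DOX+ replicate 2 or 3 or DOX- replicate 1 or 2. With the slide row as a block fibroblast, smooth muscle, Hedgehog and mitochondrial lists turned (medians -0.45, -1.18, -0.11 and 0.21).

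Some of the largest differences lay outside the lists or their named members. The chitinase-like genes Chil3 and Chil4 had log2 differences of 6.09 (SE 1.32) and 7.35 (SE 1.78), with limma adjusted p of 0.200 and 0.222, and the gel-forming mucin Muc2 4.30 (SE 1.62; 0.349). Of the 3 DOX- arrays, 2 had Chil4 and 1 had Muc2 well above background. The SD of the 3 genes within DOX+ was 2.77, 3.54 and 3.36. For Muc2 the DOX+ arrays were at -4.18, 1.39 and 1.875 and DOX- replicate 1 at -3.57, so its groups overlapped. A second Muc2 probe was not well above background on any array, with a difference of 0.235. On chromosome 11 Cuedc1 and Scpep1 had differences of 2.75 and 1.75 (limma adjusted p = 0.163 and 0.0815), and their second measured probes 0.83 and 1.5. Elobl, not well above background on any DOX- array, was at least 19.98-fold higher (limma adjusted p = 0.141).

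Transcripts of immunoglobulin segments may be higher because the DOX+ samples held more plasma cell RNA, as a hypothesis. Of 93 measured segment probes 92 were higher in DOX+, with a median difference of 2.82 (two-sided exact permutation p = 0.1 on array means, the smallest that 3 against 3 can give). These 93 of 210 probes were kept because they were well above background on all 3 arrays of at least 1 group. Probes bright in DOX+ alone thus entered through their high values there, which can tilt the count and the array means. The probes are also not independent observations. Jchain and Mzb1, genes of antibody assembly and secretion, were higher on all 3 DOX+ arrays than on all 3 DOX- arrays, and the smaller of their differences was 2.75. Jchain was at 3.18 ± 0.54 in DOX+ and -0.44 ± 3.94 in DOX- (SD, n = 3 each), so most of its spread lies within DOX-. DOX- replicate 3 was the lowest array for both genes, at -4.97 for Jchain and -6.75 for Mzb1. Across alternatives the differences of Jchain and Mzb1 were as low as 0.97 and 1.25. Neither gene passed the limma test (adjusted p = 0.447 and 0.294). The array means of the segments ran from -1.57 to 1.34 within DOX- and from 2.25 to 3.38 within DOX+.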
